A study of Mus musculus with 41 samples.

How the data were processed

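Per the submitters' processing notes, the reads were handled with fastp 0.20.1, STAR 2.7.6a, DESeq2 1.28.1 and R 4.0.2, with the genome build mm39 (GRCm39). Per the labels' protocols, total RNA was extracted with a column kit, and picogram amounts of cDNA were made into Nextera XT libraries and sequenced on an Illumina NovaSeq instrument. Read counting, strand and annotation release are not given in the sources used here. Low-input cDNA amplification can widen the spread between libraries of weakly expressed genes, and a transposase-based kit keeps no strand, so overlapping genes on opposite strands may share reads.

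The authors deposited 3 tables of comparisons, and values of single libraries were not analysed here. The mean normalised count is a signal that the authors averaged over libraries, and it is identical in all 3 tables for all 55453 genes. This points to a joint fit of all subsets, in which dispersion is shared. The log2 fold changes deposited by the authors were read as shrunken, as some are near 0 or of opposite sign beside a large Wald statistic, which an unshrunken fold cannot be. The Wald statistic is a score deposited by the authors, and their p-values equal the two-sided normal p of that score within 0.0021 on the log10 scale. The authors' adjusted p-values are absent for genes with low means, as independent filtering by the authors' tool, DESeq2, would leave them. The lowest mean with an adjusted p-value was 2.50 in TAM, 6.33 in inflammatory monocytes and 3.96 in granulocytes, so the filtering differed between comparisons. Shrinkage pulls folds of noisy genes towards 0, so a small fold beside a large Wald statistic does not show a small effect.

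For 16 genes called in TAM, 3 in inflammatory monocytes and 0 in granulocytes, the deposited log2 fold change and Wald statistic differ in sign. Direction was taken from the Wald statistic throughout, because the p-value belongs to it.

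The analysis done here counted genes with a deposited adjusted p under 0.05, compared the lists of the subsets, and tested gene lists. Overlaps were compared with n1 × n2 / N and a one-sided hypergeometric test among genes tested in both. Before the data were examined, 39 gene lists were fixed, of which 38 had at least 5 tested members. The lists were tested with limma's cameraPR on the Wald statistics with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. An estimated correlation needs values of single libraries and was not computed. List members were also counted after Benjamini-Hochberg adjustment over the list alone.

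A planned test of the difference of effects between subsets needed the standard error of each fold, which the shrunken folds do not give. In its place, and chosen after seeing the tables, opposite effects were tested by taking the larger of both p-values where the Wald signs differ and 1 where they agree, with Benjamini-Hochberg adjustment over genes tested in both.

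Named genes followed a rule fixed before the data were examined. It took genes with an adjusted p under 0.05, an absolute log2 fold change of at least 1 and a mean count of at least 50, without predicted and clone-named genes, and from these the 10 higher and 10 lower with the smallest adjusted p. Up to 4 called members per list with the smallest p were added, or up to 2 of the highest mean where none passed. Some genes that the rule takes are not reported here. Between subsets, the rule took the 10 genes with the smallest adjusted p of the planned test of differences. It was applied instead to the test of opposite directions, which was chosen after seeing the tables. The other 5 opposite genes and members of the glycolysis and immediate early lists named with them were chosen after their values were seen.

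The computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1. Alternatives tried were other thresholds, count minimums, adjustment over every gene, an empirical null, re-centring on the median gene and other list settings.

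Gene symbols are those of the tables. Transcript lengths and GC contents came from GENCODE M21, an annotation of the earlier build GRCm38, matched by symbol for 99.3% of genes tested in TAM, so no coordinates are given. Benjamini-Hochberg calls and the test of opposite directions were tried on simulated, independent Wald statistics. Of 1000 changed genes among 10000, 986 were called with the right sign and 42 unchanged genes were called, and 90 of 100 opposite genes were called. The deposited statistics had a wider spread, and real genes are not independent. Among genes with a mean count of at least 50, the robust SD was 2.72 in TAM, 1.56 in inflammatory monocytes and 2.09 in granulocytes. The counts from the simulation are therefore no error rates for the calls made here. The empirical null and re-centring were not simulated.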

Results

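MC38-luc cells, a mouse colon adenocarcinoma line that carries a luciferase gene, were grown as orthotopic tumours in the rectum of female C57BL6 mice. Treated tumours received 5 Gy in each of 5 daily fractions on days 9 to 13 after implantation, and all tumours were harvested on day 14. CD45+ CD11b+ myeloid cells were sorted into 3 subsets, and RNA of each subset was sequenced as a separate library. Tumour-associated macrophages (TAM) were sorted as Ly6C- Ly6G- F4/80+, inflammatory monocytes as Ly6C+ Ly6G-, and granulocytes as Ly6C+ Ly6G+. The series holds 41 libraries from 15 tumour numbers. TAM libraries came from 5 untreated and 10 irradiated tumours, inflammatory monocyte libraries from 5 and 9, and granulocyte libraries from 5 and 7. Untreated and irradiated libraries carry different tumour numbers, so they come from separate tumours.

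The values analysed are the authors' deposited tables of 3 comparisons, irradiated against untreated within each subset. Each table lists 55453 genes by symbol, with a mean normalised count over libraries, a shrunken log2 fold change, a Wald statistic, a p-value and an adjusted p-value. Values of single libraries were not analysed here, so the read depth of each library is unknown and no SD or standard error can be given. The Wald statistic, which is the unshrunken effect divided by its standard error, carries the error of each effect, and its sign was taken as the direction. The mean normalised count is the same in all 3 tables, so it does not describe a single subset. An adjusted p-value was present for 16851 genes in TAM, 14506 in inflammatory monocytes and 15679 in granulocytes.

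The first comparison asked which genes differed between TAM of irradiated and untreated tumours. At an adjusted p under 0.05 in the authors' deposited table, 2340 genes rose and 2108 fell, together 26.4% of the genes tested. Genes of the p53 response and of interferon signalling rose, and genes of DNA replication, mitosis and cholesterol synthesis fell. Among genes with an absolute log2 fold change of at least 1 and a mean count of at least 50, the smallest adjusted p among those that rose belonged to Rhou. The authors' deposited table gives Rhou a log2 fold change of 2.17 (Wald statistic 11.88, adjusted p = 1.3e-28). The next were Glipr2 (log2 fold change 1.75), Saa1, an acute-phase protein gene (1.28), Fam169b (2.56), Cdkn1a (2.38), Lhfpl2 (2.36), Grina (1.84), Trp53inp1 (2.98), Hif1a, the hypoxia-inducible transcription factor (1.36), and F7, coagulation factor VII (1.75), in the authors' deposited table. Among genes that fell, the authors' deposited table puts H2afx, the histone H2AX gene, first (log2 fold change -2.12, Wald statistic -11.90, adjusted p = 1.3e-28). It was followed in the authors' deposited table by Sae1 (-1.12), the histone gene H2afz (-1.11), Mcm5 (-2.53), the DNA polymerase subunit gene Pold2 (-1.61), Rbbp7 (-1.17), Mcm6 (-2.07), Mcm3 (-1.77), the centromere histone gene Cenpa (-1.98) and Rrm1 (-1.95).

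**Figure D1:**
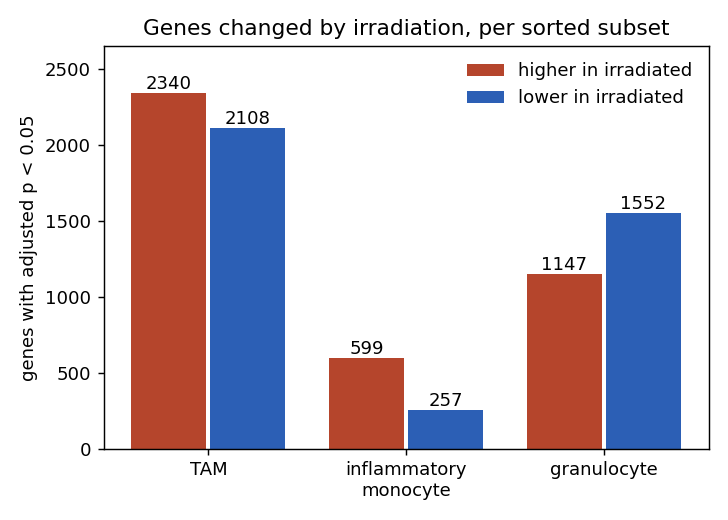
Number of genes (y axis) past an adjusted p of 0.05 in each sorted subset (x axis), with separate bars for genes higher and lower in irradiated tumours, in the authors' deposited tables. TAM had 2340 higher and 2108 lower genes, inflammatory monocytes 599 and 257, and granulocytes 1147 and 1552.

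Of 28 tested targets of p53, the transcription factor activated by DNA damage, 23 rose in TAM and none fell (25 rose and 1 fell adjusted over the list alone). The list stood above the other tested genes (adjusted p = 2.9e-20, limma's cameraPR). Cdkn1a, a cyclin-dependent kinase inhibitor, Ccng1 (log2 fold change 1.97) and Mdm2, which degrades p53 (1.58), were among them in the authors' deposited table. Of 38 genes of the type I interferon response, 34 rose and none fell (36 rose adjusted over the list alone; cameraPR adjusted p = 1.9e-14). Per the authors' deposited table, log2 fold changes were 1.84 for Oas3, an antiviral nucleotide synthase gene, 2.08 for Rsad2, which encodes viperin, and 1.82 for the interferon regulatory factor gene Irf7. Of 29 interferon gamma response genes, 11 rose and 1 fell, with the same counts adjusted over the list alone (cameraPR adjusted p = 0.0051, and 0.050 with a preset correlation of 0.05). Among them were Cd274, which encodes the checkpoint ligand PD-L1 (1.37), and Socs1 (1.13), in the authors' deposited table. Genes of MHC class I presentation rose in 10 of 16 cases and none fell (11 rose adjusted over the list alone; cameraPR adjusted p = 3.9e-06). H2-Q6, a class Ib gene, had a log2 fold change of 2.30 and H2-K1 of 0.89 in the authors' deposited table. MHC class II genes showed no such call, as 1 of 12 rose and no shift of the list was detected (1 adjusted over the list alone; cameraPR adjusted p = 0.59).

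All 32 tested genes of S phase and DNA replication fell in TAM (32 adjusted over the list alone; cameraPR adjusted p = 3.1e-42), and so did all 30 of mitosis (30 adjusted over the list alone; adjusted p = 5.3e-30). The authors' deposited table gives log2 fold changes of -2.28 for the proliferation marker Mki67, -2.85 for the mitotic kinesin Kif23 and -2.25 for Cdca8. Of 27 DNA damage repair genes, 19 fell and 1 rose (21 fell and 1 rose adjusted over the list alone; cameraPR adjusted p = 2.2e-09). Xrcc6, which encodes Ku70, fell by a log2 fold change of -1.02 and Fanci by -2.79 in the authors' deposited table. Genes of cholesterol synthesis fell in 15 of 19 cases and none rose (17 fell adjusted over the list alone; cameraPR adjusted p = 1.8e-12). Sqle, which encodes squalene epoxidase, had -1.87 and Idi1 -1.79 in the authors' deposited table. In the list of lipid handling and lysosome genes, 17 of 26 rose and none fell (18 rose and 1 fell adjusted over the list alone; cameraPR adjusted p = 8.5e-08). They included the cholesterol exporter gene Abca1 (1.29) and Plin2, a lipid droplet coat gene (1.27), in the authors' deposited table.

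Immediate early and heat shock genes rose in 19 of 27 cases in TAM and none fell (19 rose and 1 fell adjusted over the list alone; cameraPR adjusted p = 2.4e-14). Dusp1, a MAP kinase phosphatase gene, had a log2 fold change of 1.83, Ier5 of 1.43 and Zfp36, which encodes an RNA-binding protein that destabilises cytokine mRNAs, of 1.26 in the authors' deposited table. NF-kB feedback and survival genes rose in 14 of 21 cases (14 rose and 1 fell adjusted over the list alone; cameraPR adjusted p = 8.8e-09), among them the inhibitor gene Nfkbia with 1.27 in the authors' deposited table. Of 20 inflammatory cytokines and enzymes, 11 rose and none fell (12 rose adjusted over the list alone; cameraPR adjusted p = 5.6e-07). Il1rn, the interleukin 1 receptor antagonist, had a log2 fold change of 1.90, Il1b of 1.50, Ptgs2, which encodes cyclooxygenase 2, of 1.23 and Il6 of 1.51 in the authors' deposited table. Hypoxia and glycolysis genes rose in 9 of 25 cases and none fell (11 rose adjusted over the list alone). Vegfa had a log2 fold change of 1.50 and Pfkfb3 of 1.29 in the authors' deposited table. That list's cameraPR adjusted p was 0.0094, and 0.055 with a preset correlation of 0.05.

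Markers of other cell types moved in the TAM comparison as well. Classical monocyte markers rose in 8 of 13 cases (9 adjusted over the list alone; cameraPR adjusted p = 2.7e-07), with a log2 fold change of 1.96 for Ly6c2 in the authors' deposited table. Eosinophil markers rose in 4 of 7 cases (6 adjusted over the list alone; cameraPR adjusted p = 0.0069), with 2.48 for Siglecf and 3.03 for Prg2 in the authors' deposited table. Neutrophil markers had a positive Wald statistic past the threshold in 14 of 16 cases (15 adjusted over the list alone; cameraPR adjusted p = 1.4e-10), but 5 of these carry a negative shrunken log2 fold change. Secondary granule genes did so in 11 of 14 cases, 3 of them with a negative fold (14 adjusted over the list alone; cameraPR adjusted p = 1.2e-12). For the secondary granule gene Ngp, the authors' deposited table gives a Wald statistic of 9.20 beside a log2 fold change of -0.59, and for Camp 8.66 beside -0.77. The direction of such genes is therefore uncertain. Csf3r, the receptor for granulocyte colony-stimulating factor, had both values positive in the authors' deposited table (log2 fold change 1.36, Wald statistic 6.77). Dendritic cell markers fell in 7 of 14 cases and rose in 1, with the same counts adjusted over the list alone, and Batf3, a factor of cross-presenting dendritic cells, had -1.25 in the authors' deposited table. Their cameraPR adjusted p was 0.014, and 0.054 with a preset correlation of 0.05. Epithelial and tumour cell markers stood above other genes, with 2 of 16 that rose and a median log2 fold change of 1.28 (0 adjusted over the list alone; cameraPR adjusted p = 0.0049). Cdh1, which encodes E-cadherin, had 0.99 and Phgr1 1.71, the latter at a mean count of only 8.8, in the authors' deposited table. Fibroblast markers fell in 4 of 14 cases (5 adjusted over the list alone), with -1.77 for Col1a1 in the authors' deposited table. Their cameraPR adjusted p was 0.043, and 0.10 with a preset correlation of 0.05. Ribosomal protein genes fell in 69 of 81 cases and none rose (70 fell adjusted over the list alone; cameraPR adjusted p = 7.4e-26), with a median log2 fold change of -0.58. Mitochondrial transcripts fell in 7 of 12 cases (7 adjusted over the list alone; cameraPR adjusted p = 0.0011). Of 15 housekeeping genes fixed as a control list, 5 fell and 2 rose (5 and 2 adjusted over the list alone), with -1.19 for Tubb5 and -0.77 for Ppia in the authors' deposited table. The control list's cameraPR adjusted p was 0.015, and 0.055 with a preset correlation of 0.05.

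Calls in TAM rest on the authors' Wald test. When Wald statistics were divided by their own robust SD, 98 genes passed (42 higher and 56 lower), and with an absolute log2 fold change of at least 1 as a further criterion 1657 did. Re-centring on the median gene gave 2088 higher and 2341 lower genes in place of 2340 and 2108. That setting approximated each standard error by the shrunken fold over the Wald statistic, which the shrinkage distorts. It therefore cannot decide which direction held more genes, and the small excess of higher genes was not tested otherwise.

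**Figure D2:**
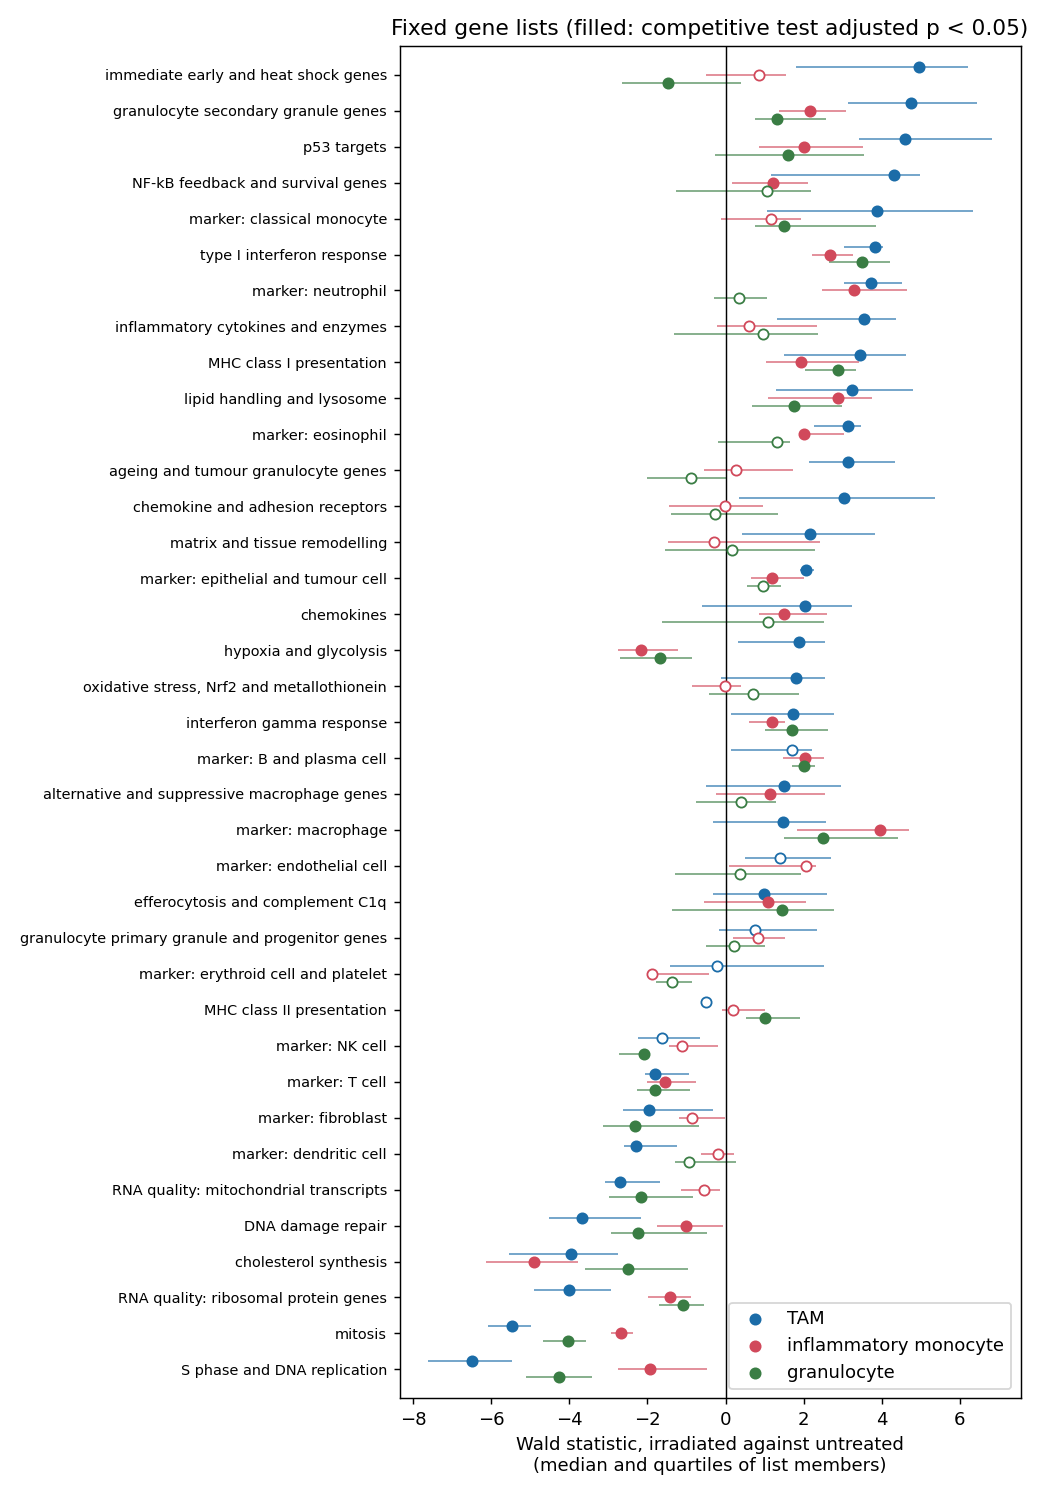
Median Wald statistic (x axis, irradiated against untreated; lines span the quartiles of list members) for gene lists fixed before the data were examined (y axis), in the 3 subsets by colour. Filled points mark lists with a cameraPR adjusted p under 0.05. Medians of S phase genes were -6.50 in TAM, -1.94 in inflammatory monocytes and -4.26 in granulocytes, and those of immediate early genes were 4.95, 0.85 and -1.47.

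For inflammatory monocytes, the Ly6C+ cells from which tumour macrophages can arise, the same question gave 599 genes that rose and 257 that fell, 5.9% of those tested. Macrophage genes and part of the interferon response genes and p53 targets rose, and cholesterol synthesis genes fell. Among genes with an absolute log2 fold change of at least 1 and a mean count of at least 50, Mertk, a receptor for apoptotic cells, had the smallest adjusted p of those that rose (log2 fold change 1.91, Wald statistic 9.09, adjusted p = 2.8e-16 in the authors' deposited table). F7 (1.63), the ectoenzyme gene Cd38 (2.24), Cd84 (1.04), Fam169b (1.88), P2ry14 (1.89), the folate receptor gene Folr2 (2.18), Slc27a1 (1.41), H2-Q6 (2.18) and Phlda3 (2.75) followed in the authors' deposited table. Among genes that fell, 8 of the 10 with the smallest adjusted p, all but Amz1 and Cadm1, act in sterol synthesis or transport. Log2 fold changes in the authors' deposited table were -1.29 for Msmo1 (adjusted p = 5.2e-13), -1.58 for Cyp51, -1.80 for Idi1, -1.39 for Fdft1, -1.52 for Stard4, -1.79 for Sqle, -1.56 for Amz1, -2.54 for Cadm1, -2.00 for Hsd17b7 and -1.12 for Hmgcs1.

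Cholesterol synthesis genes fell in 15 of 19 cases in inflammatory monocytes and none rose (16 adjusted over the list alone; cameraPR adjusted p = 2.2e-32). Of 38 type I interferon response genes, 15 rose and none fell (31 rose adjusted over the list alone; cameraPR adjusted p = 4.9e-17), with log2 fold changes of 1.58 for Ifi44 and 1.40 for Irf7 in the authors' deposited table. Of 28 p53 targets, 8 rose and none fell (11 adjusted over the list alone; cameraPR adjusted p = 3.6e-09), with 2.38 for Psrc1 and 1.20 for Ccng1 in the authors' deposited table. Of 29 interferon gamma response genes, 3 rose (3 adjusted over the list alone; cameraPR adjusted p = 0.006, and 0.056 with a preset correlation of 0.05). MHC class I genes rose in 6 of 16 cases (7 adjusted over the list alone; cameraPR adjusted p = 2.9e-07) and MHC class II genes in 1 of 12 (1 adjusted over the list alone; adjusted p = 0.52). Macrophage markers rose in 9 of 14 cases and none fell (9 adjusted over the list alone; cameraPR adjusted p = 1.9e-12). They included the complement genes C1qa (log2 fold change 1.26) and C1qb (1.08), Ms4a7 (1.36) and Adgre1, which encodes F4/80 (0.74), in the authors' deposited table. Lipid handling and lysosome genes rose in 13 of 26 cases (15 rose and 1 fell adjusted over the list alone; cameraPR adjusted p = 1.1e-09), with Apoe at 1.27 and Grn at 0.82 in the authors' deposited table.

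S phase genes fell in 6 of 32 cases in inflammatory monocytes (14 adjusted over the list alone; cameraPR adjusted p = 6.1e-08) and mitosis genes in 7 of 30 (28 adjusted over the list alone; adjusted p = 4.9e-17). Uhrf1 had a log2 fold change of -1.40 and Aurkb, which encodes a mitotic kinase, of -1.33 in the authors' deposited table. Hypoxia and glycolysis genes fell in 6 of 25 cases and none rose (11 fell adjusted over the list alone; cameraPR adjusted p = 8.5e-11), with -1.15 for the prolyl hydroxylase gene Egln3 and -0.76 for the glucose transporter gene Slc2a1 in the authors' deposited table. Immediate early and heat shock genes gave 2 that rose and 2 that fell (2 and 2 adjusted over the list alone; cameraPR adjusted p = 0.51). The heat shock genes Hspa1b (-2.04) and Hspa1a (-1.49) were the ones that fell in the authors' deposited table. No member of the NF-kB list passed over all genes (0 adjusted over the list alone), while the list's cameraPR adjusted p was 0.031, and 0.11 with a preset correlation of 0.05. Nfkbia had a log2 fold change of 0.14 with an adjusted p of 0.8 in the authors' deposited table.

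Neutrophil markers rose in 9 of 16 cases in inflammatory monocytes (14 adjusted over the list alone; cameraPR adjusted p = 1.2e-12), with log2 fold changes of 2.77 for S100a8 and 1.99 for S100a9 in the authors' deposited table. Secondary granule genes rose in 4 of 14 cases (7 adjusted over the list alone; adjusted p = 4.7e-08). Olfm4, one of them, had a Wald statistic of 9.31 beside a log2 fold change of 0.11 in the authors' deposited table. B and plasma cell markers rose in 3 of 12 cases (3 adjusted over the list alone; cameraPR adjusted p = 0.00029) and eosinophil markers in 2 of 7 (3 adjusted over the list alone; adjusted p = 0.0012). Ribosomal protein genes fell in 2 of 79 cases (1 adjusted over the list alone; cameraPR adjusted p = 1.1e-09), with a median log2 fold change of -0.22. In the control list of housekeeping genes 2 of 15 fell and 1 rose (4 and 1 adjusted over the list alone; cameraPR adjusted p = 0.013, and 0.055 with a preset correlation of 0.05). Division of Wald statistics by their robust SD left 29 genes called, and Benjamini-Hochberg adjustment over every gene with a p-value left 543.

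**Figure D3:**
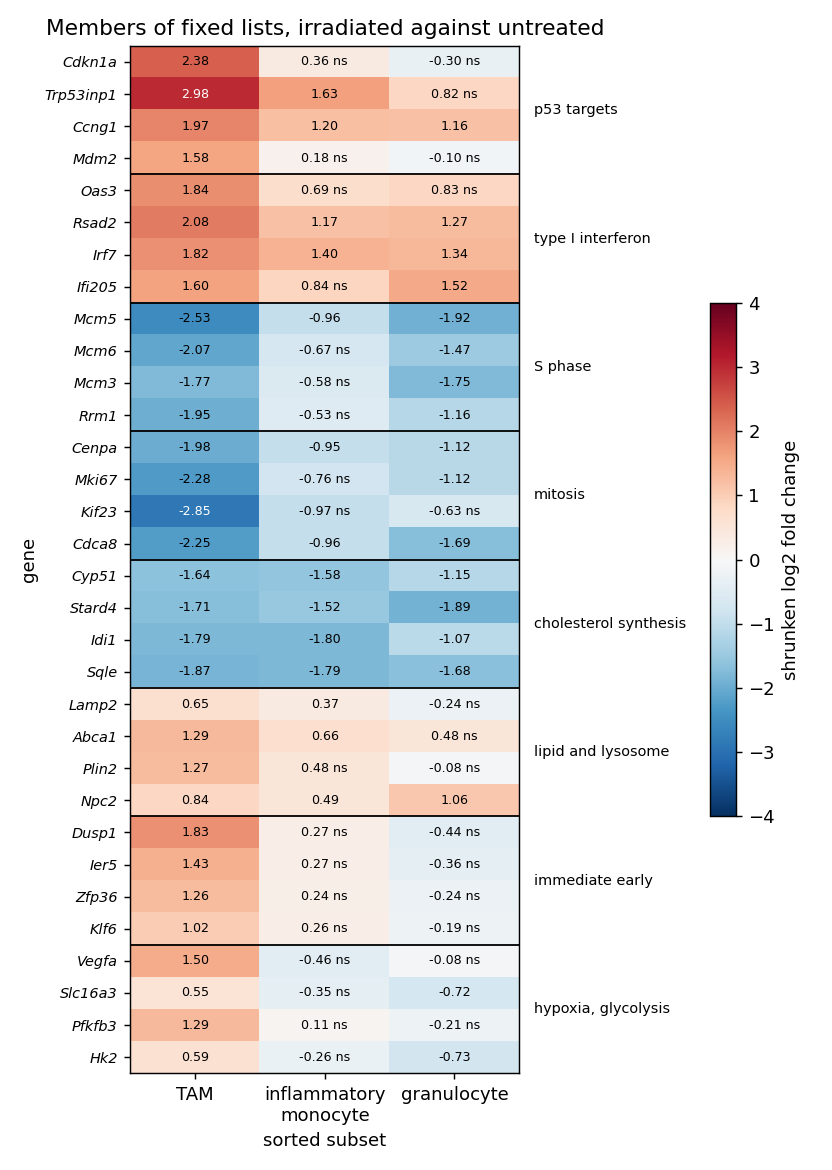
Shrunken log2 fold changes, irradiated against untreated (colour and printed value, from the authors' deposited tables), of the members of 8 fixed gene lists with the smallest p in TAM (rows, grouped by list) in the 3 subsets (columns); ns marks an adjusted p of 0.05 or more. Cyp51 had -1.64 in TAM, -1.58 in inflammatory monocytes and -1.15 in granulocytes, while Slc16a3 had 0.55 in TAM and -0.72 in granulocytes.

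In granulocytes, 1147 genes rose and 1552 fell, 17.2% of those tested. Type I interferon response genes rose, as did part of the interferon gamma response genes, macrophage markers and p53 targets. Genes of DNA replication and mitosis fell, as did part of the cholesterol synthesis and glycolysis genes. Ikbke, which encodes a kinase of interferon and NF-kB signalling, had the smallest adjusted p of those that rose under the same fold and mean count criteria (log2 fold change 2.19, Wald statistic 9.52, adjusted p = 2.6e-17 in the authors' deposited table). It was followed by the lysosomal nuclease gene Dnase2a (1.13), Slc2a9 (2.60), Mfsd7a (2.95), Dpep2 (1.77), Mertk (1.58), Gas7 (1.36), Cd38 (2.06), the p53-induced nuclease gene Aen (1.36) and the chemerin receptor gene Cmklr1 (1.37) in the authors' deposited table. Coq10b led those that fell under these criteria (log2 fold change -1.43, Wald statistic -8.62, adjusted p = 3.6e-14 in the authors' deposited table). Mcm3 (-1.75), Vps37b (-1.69), Srrd (-1.39), Gcat (-2.56), Stard4 (-1.89), Usp36 (-1.62), Selenon (-1.30), Rnf11 (-1.11) and the kinase gene Braf (-1.41) came next in the authors' deposited table.

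Type I interferon response genes rose in 28 of 38 cases in granulocytes and none fell (31 adjusted over the list alone; cameraPR adjusted p = 1.2e-19). Ifit1 had a log2 fold change of 1.96 and Mx1 of 2.10 in the authors' deposited table. Interferon gamma response genes rose in 7 of 29 cases and none fell (10 adjusted over the list alone; cameraPR adjusted p = 3.1e-05), with 1.32 for the chemokine gene Cxcl10 in the authors' deposited table. MHC class I genes rose in 9 of 16 cases (12 adjusted over the list alone; cameraPR adjusted p = 6.0e-08). The MHC class II presentation list also stood above other genes in this subset (cameraPR adjusted p = 0.012, and 0.040 with a preset correlation of 0.05). Of its 12 genes, 2 rose (2 adjusted over the list alone), namely Ctss (0.98) and Ifi30 (0.64) in the authors' deposited table. The other 10, among them H2-Aa, H2-Ab1 and Cd74, were not called. Ctss was also the single member called in TAM and in inflammatory monocytes. Of 28 p53 targets, 9 rose and 2 fell (11 rose and 2 fell adjusted over the list alone; cameraPR adjusted p = 2.7e-05), with 1.61 for Zmat3 and 0.96 for Ei24 in the authors' deposited table. Cdkn1a had a log2 fold change of -0.30 in granulocytes in the authors' deposited table and did not pass. S phase genes fell in 26 of 32 cases (29 adjusted over the list alone; cameraPR adjusted p = 4.0e-23) and mitosis genes in 28 of 30 (29 adjusted over the list alone; adjusted p = 1.9e-21). Top2a, the replication-associated topoisomerase gene, had -2.89 and Birc5, which encodes survivin, -2.93 in the authors' deposited table. Of 27 DNA damage repair genes, 11 fell and none rose (14 adjusted over the list alone; cameraPR adjusted p = 4.9e-05), with -1.29 for Xrcc6 in the authors' deposited table. Cholesterol synthesis genes fell in 8 of 19 cases and 1 rose (10 fell and 1 rose adjusted over the list alone; cameraPR adjusted p = 4.1e-05).

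Hypoxia and glycolysis genes fell in 8 of 25 cases in granulocytes and none rose (9 adjusted over the list alone; cameraPR adjusted p = 5.5e-05). Slc2a1 had a log2 fold change of -0.92, the lactate dehydrogenase gene Ldha -0.69 and the lactate exporter gene Slc16a3 -0.72 in the authors' deposited table. Immediate early and heat shock genes fell in 7 of 27 cases and 1 rose (8 fell and 1 rose adjusted over the list alone). Their cameraPR adjusted p was 0.042, and 0.16 with a preset correlation of 0.05. Atf3, a stress-induced transcription factor, had -0.85 and Klf4 1.08 in the authors' deposited table. Inflammatory cytokines and enzymes went both ways, 4 up and 4 down of 20 (6 and 4 adjusted over the list alone; cameraPR adjusted p = 0.28). Tnf (1.03) and Nos2, the inducible nitric oxide synthase gene (1.90), rose, while Osm (-1.02) and Ptgs2 (-0.89) fell, in the authors' deposited table. Among genes of alternative and suppressive macrophages, Arg1, which encodes arginase 1 (1.28), and Il10 (2.84) rose and Entpd1, the ectonucleotidase gene for CD39 (-0.87), fell in the authors' deposited table. In all 4 of 26 rose and 2 fell (4 and 2 adjusted over the list alone), and no shift of the list was detected (cameraPR adjusted p = 0.19). In TAM 8 rose and 2 fell (8 and 3 adjusted over the list alone, cameraPR adjusted p = 0.014). In inflammatory monocytes 5 rose and none fell (7 and 0 adjusted over the list alone, cameraPR adjusted p = 0.006). With a preset correlation of 0.05 these were 0.069 and 0.055. Arg1 rose there too, with 0.88 and 0.62 in the authors' deposited tables.

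Macrophage markers rose in 7 of 14 cases in granulocytes (8 adjusted over the list alone; cameraPR adjusted p = 1.6e-06) and classical monocyte markers in 5 of 13 (5 adjusted over the list alone; adjusted p = 2.5e-05). Fcgr1 had a log2 fold change of 1.27 and Ly6c2 of 1.82 in the authors' deposited table. Neutrophil markers did not stand apart in this subset, with 1 that rose and 1 that fell of 16 (1 and 1 adjusted over the list alone; cameraPR adjusted p = 0.58). Secondary granule genes did, with 4 of 14 that rose and none that fell (4 adjusted over the list alone; cameraPR adjusted p = 0.00084). The 4 were Cybb, Chil3, Lyz2 and Mmp8, of which Chil3 is also on the classical monocyte list and Mmp8 on the neutrophil list. Camp, Ngp, Ltf and Lcn2 were not called, so the shift need not be one of granule genes as such. Fibroblast markers fell in 6 of 13 cases (7 adjusted over the list alone; adjusted p = 0.006) and NK cell markers in 4 of 11 (5 adjusted over the list alone; adjusted p = 0.0018). Mitochondrial transcripts fell in 4 of 12 cases (6 adjusted over the list alone; adjusted p = 0.0074), and ribosomal protein genes in 7 of 80 with 2 that rose (6 and 1 adjusted over the list alone). The ribosomal list had a cameraPR adjusted p of 0.0043, and 0.11 with a preset correlation of 0.05. Housekeeping genes gave 2 of 15 that fell and 1 that rose (2 and 1 adjusted over the list alone; cameraPR adjusted p = 0.21). After division of Wald statistics by their robust SD 14 genes passed, and 1158 had an absolute log2 fold change of at least 1.

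Comparing the subsets, genes called in the same direction overlapped beyond what independent lists would give. TAM and inflammatory monocytes shared 347 genes that rose, where 93.8 would be expected of independent lists among 14506 genes tested in both (one-sided hypergeometric p = 5.2e-131), and 156 that fell against 36.8 (p = 1.9e-67). TAM and granulocytes shared 492 that rose against 169.1 expected (p = 2.5e-129) and 616 that fell against 207.4 (p = 5.9e-170). Inflammatory monocytes and granulocytes shared 266 that rose against 46.7 (p = 4.4e-141) and 127 that fell against 27.1 (p = 1.2e-56). Across all 3 subsets, 182 genes rose and 100 fell in each, where 7.3 and 3.9 would be expected. The subsets were sorted from the same tumours, and genes are not independent of each other, so part of these overlaps may follow differences between tumours. RNA of one subset in the gate of another could also give shared calls and was not measured here. Neutrophil markers were called higher in 14 of 16 cases in TAM (5 with a negative fold) and in 9 of 16 in inflammatory monocytes. Macrophage markers were called higher in 9 of 14 cases in inflammatory monocytes and in 7 of 14 in granulocytes. No member of these lists fell in those comparisons. Mertk, Cd38, F7 and Irf7 were called higher in all 3 subsets, and Cyp51, Sqle, Stard4 and Mcm5 were called lower in all 3. Mertk is a member of the macrophage marker list.

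Whether an effect differed between subsets was tested for genes that moved in opposite directions, with the larger of both p-values and Benjamini-Hochberg adjustment. This test found 15 genes, all higher in TAM and lower in granulocytes of irradiated tumours. At an adjusted p under 0.01 the test left 5 genes, and with Wald statistics divided by their robust SD it left 0. The 15 were Braf, Gla, Cpeb2, Sik1, Socs3, Tnfaip6, Atf3, Csrnp1, Chd7, Mcl1, Nfil3, Prxl2c, Slc49a4, Mef2d and Chp1. Braf had the smallest adjusted p (0.0016), with log2 fold changes of 0.99 in TAM and -1.41 in granulocytes in the authors' deposited tables. Socs3, a feedback inhibitor of cytokine signalling, had 1.09 and -1.16, and Mcl1, an anti-apoptotic gene, 0.99 and -0.63 in the authors' deposited tables. With both deposited adjusted p-values under 0.05, 193 genes were higher in TAM and lower in granulocytes and 9 were the other way, against 228.9 and 153.3 expected of independent lists. These counts were 11 and 0 with an absolute log2 fold change of at least 1 in both, and 302 and 32 at adjusted p-values under 0.1. The 193 included 11 of 52 tested members of the glycolysis and immediate early lists, namely Atf3, Egln3, Egr1, Fosl2, Hk2, Ier3, Jun, Junb, Pfkl, Slc16a3 and Slc2a1. Il1b had a log2 fold change of 1.50 in TAM and -0.72 in granulocytes, and Ptgs2 1.23 and -0.89, in the authors' deposited tables, and neither is among the 15. Other members of the inflammatory list were called higher in both subsets, with 0.92 and 1.03 for Tnf, 1.80 and 1.90 for Nos2 and 1.51 and 1.01 for Il6 in the authors' deposited tables. No gene passed the test of opposite directions between TAM and inflammatory monocytes (132 at an unadjusted p under 0.05; 21 with both deposited adjusted p-values under 0.05) or between inflammatory monocytes and granulocytes (66 and 3). Effects of the same direction but different size were not tested.

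**Figure D4:**
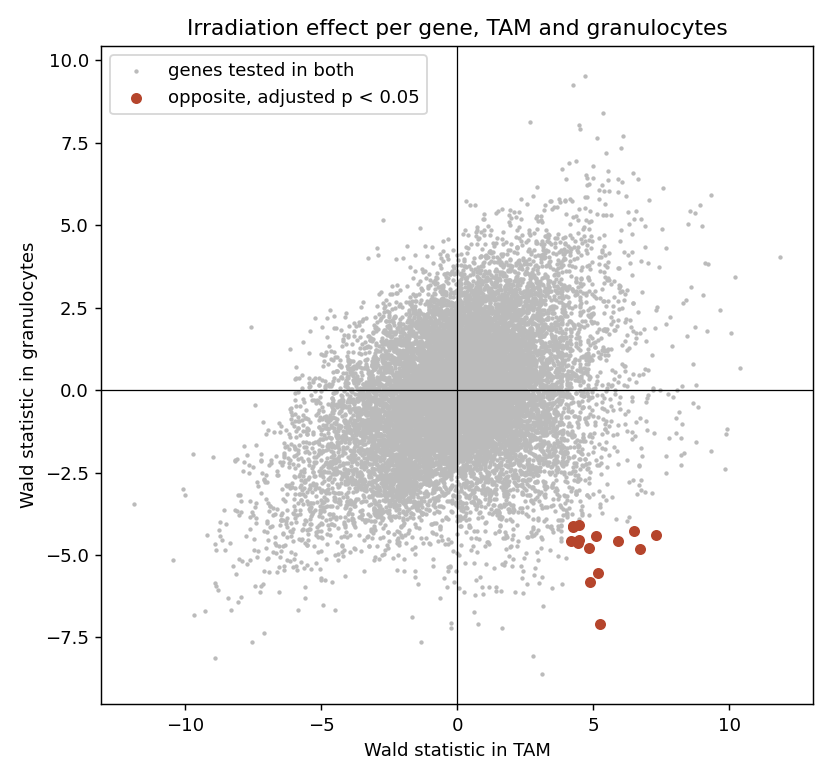
Wald statistics of irradiation in TAM (x axis) and in granulocytes (y axis) for the 15679 genes tested in both, from the authors' deposited tables. The 15 genes past the test of opposite directions, in colour, all lie at positive values in TAM and negative values in granulocytes.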

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

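The tests of tumour handling and of granulocyte RNA, the marker test of sign differences and the mitosis test were chosen after the result was seen. The tests of mean count, transcript length and GC content were set before. Earlier versions of the tests of handling and of granulocyte RNA were replaced. The median Wald statistic of the immediate early list in granulocytes, -1.47 with quartiles of -2.65 and 0.40, did not decide on handling. Counts of granulocyte list members among opposite genes, 0 of 61 in the set of 15 and 3 of 61 in the set of 193 called higher in TAM and lower in granulocytes, did not decide. A comparison with the median of the 193 was void because those genes were selected by the TAM threshold. A test of over-representation of the glycolysis and immediate early lists (one-sided Fisher exact p = 0.049 among the 15 and 2.9e-11 among 193) was set aside, because those lists had been picked for the pattern.

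The 10 genes with the smallest adjusted p in the test of opposite directions between TAM and granulocytes are given here. That test was chosen after seeing the tables. Each gene has its TAM minus granulocyte difference of log2 fold changes from the authors' deposited tables. The differences were 1.63 for Atf3 (0.78 against -0.85), 2.40 for Braf (0.99 against -1.41), 1.91 for Chd7 (0.90 against -1.01), 2.55 for Cpeb2 (1.12 against -1.43) and 2.20 for Csrnp1 (1.14 against -1.06). They were 2.33 for Gla (1.09 against -1.24), 1.62 for Mcl1 (0.99 against -0.63), 2.22 for Sik1 (1.27 against -0.95), 2.25 for Socs3 (1.09 against -1.16) and 2.92 for Tnfaip6 (1.62 against -1.30). Adjusted p-values of the test of opposite directions lay between 0.0016 and 0.018.

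Handling of the tumours that acts on all sorted subsets alike would move these genes the same way in both subsets. The granulocyte Wald statistics of all 15 opposite genes were -4.08 or lower. Those genes were selected for opposite signs, so this outcome was fixed by the selection and cannot argue against handling. It adds nothing to the test of opposite directions, which left 0 genes under the empirical null. Handling that acts on the subsets differently was not tested. Granulocyte RNA in the TAM gate of irradiated tumours, a gate that excludes Ly6G+ cells, stays open: neutrophil markers without the 5 of discordant sign had a median Wald statistic of 3.58 in TAM, while S100a9 and S100a8 had 4.16 and 2.99 beside log2 fold changes of -1.24 and -0.05 in the authors' deposited table. Levels per subset, which would size such a carry-over, were not analysed here, and a response to irradiation that differs between the subsets stays open as an untested hypothesis.

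Among called genes of TAM, 16 had a positive Wald statistic and a negative shrunken log2 fold change, among them Ngp, Camp, Olfm4 and S100a9, whose products are abundant in neutrophils. Low expression in TAM stays open as the cause: their median mean count of 329.1 is above the bound of 50 set beforehand, but that bound was wrong, since the mean is pooled over all subsets. Shrinkage in a joint fit over subsets that express a gene at very different levels is a candidate explanation, since neutrophil and secondary granule list members were over-represented among the 16 (6 of 19 called members, one-sided Fisher exact p = 2.0e-11). Those lists were chosen after such genes had been seen among the 16, so this is not independent evidence. Under this explanation the Wald sign is the better guide, but values of single libraries would be needed to decide, and no biological explanation was tested.

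Ribosomal protein genes fell in 69 of 81 cases in TAM, with a median Wald statistic of -4.01 and an upper quartile of -2.95. Loss of short transcripts was examined with 330 other genes matched on annotated transcript length and mean count. Their median Wald statistic was -0.49 (quartiles -2.61 and 1.61), and their median length was 1187.5 against 1094 for ribosomal protein genes. This argues against an effect of annotated length alone. Longer transcripts stood slightly higher across 16504 other genes (Spearman correlation 0.097). A GC effect is argued against in the same way, with a median of 0.65 over 393 genes matched on GC content and mean count. Both matchings used a mean count pooled over all subsets, so levels in TAM were not matched. Fewer dividing cells stay open as a cause: the ratio of ribosomal to mitosis medians in granulocytes was 0.36 times that in TAM, but the subsets need not share a ratio. A difference between libraries in depth or RNA quality was not tested, mitochondrial transcripts fell in 7 of 12 cases beside them, and an effect of irradiation on ribosomal genes stays open as a hypothesis.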

How the results depend on the processing

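The setting without genes of discordant sign was chosen after seeing the data. At an adjusted p under 0.01, calls numbered 2918 in TAM, 369 in inflammatory monocytes and 1420 in granulocytes, and opposite genes between TAM and granulocytes 5. With an absolute log2 fold change of at least 1 the counts were 1657, 360 and 1158, and overlaps of same-direction calls were 189 for TAM and inflammatory monocytes, 487 for TAM and granulocytes and 144 for inflammatory monocytes and granulocytes. Opposite calls of TAM and granulocytes went from 202 to 11, and to 334 at an adjusted p under 0.1. At an adjusted p under 0.1, inflammatory monocytes had 1343 calls, and their overlaps were 782 with TAM and 644 with granulocytes. Adjustment over every gene with a p-value left 543 calls in inflammatory monocytes. These settings add or remove genes by construction. Under the empirical null, Wald statistics centred on their median and divided by their robust SD, calls numbered 98, 29 and 14 and opposite genes 0. That setting takes the bulk of genes as unchanged, and the wide spread it removes can hold real effects. The cause of the spread was not tested. The setting took its median and robust SD over all genes with an adjusted p-value. Robust SDs were 2.72, 1.56 and 2.09 among genes with a mean count of at least 50, a different set. Of 390 named gene results, 299 lost their call under it. With a preset correlation of 0.05, 21 gene lists passed in TAM in place of 32. Re-centring on the median gene turned the TAM split from 2340 higher and 2108 lower to 2088 and 2341. Its standard errors were approximated from shrunken folds, so this change of split is not reliable. Removing genes of discordant sign left 4432, 853 and 2699 calls. No list reversed under the list settings, and no named gene under adjustment over every gene, the empirical null or re-centring, the settings computed for them. Adjustment cannot change a sign, and re-centring moved folds only by their medians (0.039 in TAM, 0.015 in inflammatory monocytes and -0.013 in granulocytes). A list counted as reversed only if it passed in both settings, so the lack of reversals is weak evidence. No paired analysis was possible because untreated and irradiated tumours carry different numbers and the tables hold comparisons, not libraries. For the same reason other tools, scalings and filters, leaving out libraries and other splits of the samples were not run, and the limit set by read depth is unknown.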

Other observations

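In TAM, matrix and tissue remodelling genes rose in 11 of 25 cases and fell in 2 (12 and 2 adjusted over the list alone; cameraPR adjusted p = 0.0011), with log2 fold changes of 1.74 for the matricellular gene Thbs1 and 1.74 for Ecm1 in the authors' deposited table. Chemokine and adhesion receptors rose in 11 of 20 cases and fell in 2 (11 and 2 adjusted over the list alone; cameraPR adjusted p = 5.3e-05), with 2.05 for Cxcr4 in the authors' deposited table. The list of ageing and tumour granulocyte genes rose in 13 of 20 cases in TAM (15 adjusted over the list alone; cameraPR adjusted p = 4.3e-08) and went both ways in granulocytes, with 2 that rose and 3 that fell (2 and 3 adjusted over the list alone; adjusted p = 0.52). Of 26 efferocytosis and complement genes, 7 rose and 1 fell in TAM, 5 rose in inflammatory monocytes, and 7 rose and 1 fell in granulocytes (7 and 1, 5, and 9 and 1 adjusted over the list alone). The list's cameraPR adjusted p was 0.012, 0.0015 and 0.0023 in this order, but 0.064, 0.071 and 0.061 on ranks, and in TAM 0.064 with a preset correlation of 0.05. Complement factor C3 had a log2 fold change of 2.46 in TAM, and factor B, Cfb, had 1.43 in inflammatory monocytes and 1.79 in granulocytes, in the authors' deposited tables.

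Few B and plasma cell markers passed in any subset. In inflammatory monocytes 3 of 12 rose, among them Cd22 with a log2 fold change of 1.53 and Cd79a with 2.17 in the authors' deposited table. In granulocytes 2 of 13 rose (1 adjusted over the list alone; cameraPR adjusted p = 0.0017), among them Pax5 with 2.56 at a mean count of 5.93 in the authors' deposited table. In TAM 2 of 13 rose and 1 fell (2 and 1 adjusted over the list alone; cameraPR adjusted p = 0.24), with 1.53 for Igkc, 0.99 for Fcer2a and -1.98 for Ighm in the authors' deposited table. T cell markers stood below other genes in all 3 subsets, with cameraPR adjusted p-values of 0.043 in TAM, 0.00086 in inflammatory monocytes and 0.026 in granulocytes, and of 0.11, 0.0079 and 0.091 with a preset correlation of 0.05. Of their members, 2 of 16 fell and 1 rose in TAM, 0 of 15 passed in inflammatory monocytes, and 2 of 16 fell and 1 rose in granulocytes (1 and 1, 0, and 2 and 1 adjusted over the list alone). Cd34, a progenitor marker, fell in all 3 subsets, with log2 fold changes of -1.05 in TAM, -1.26 in inflammatory monocytes and -2.06 in granulocytes in the authors' deposited tables. Its list of primary granule and progenitor genes showed no shift in any of them (cameraPR adjusted p = 0.21, 0.51 and 0.86). Other called members rose, with 2.33 for Cebpe, 1.12 for Prtn3 and 1.25 for Serpinb1a in TAM and 1.08 for Prtn3 in granulocytes in the authors' deposited tables. For erythroid and platelet markers in TAM, and matrix genes in inflammatory monocytes, the list median and the direction of the list test differed in sign, and neither test passed.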
